A study of Danio rerio with 6 samples.

How the data were processed

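RNA was sequenced from whole zebrafish embryos at 48 hours post-fertilization, in 3 wildtype and 3 homozygous dnajc21 mutant libraries. Per the labels' protocols, each RNA sample came from 30 to 50 embryos lysed in Trizol, samples with an RNA integrity number of at least 8 were kept, poly-A RNA was enriched from 2 µg of total RNA, fragmented with RNase III, and 50 ng of it entered the library. Per the submitters' processing notes, STAR and RSEM were used with genome build danRer11, and DESeq2 is also named; versions and the gene annotation are not given. The authors deposited 1 table of RSEM expected counts per gene and library, not normalized between libraries. It has 35197 rows, of which 30781 have a count above 0, and 18.8% of its values are not whole numbers (tolerance 0.005), as happens where reads are shared between rows. Total counts ran from 8600951 to 11798543, and 26100 to 26846 rows were detected per library. A count of 0 allows up to 3 counts, or 0.254 to 0.349 CPM depending on the library; this covers counting error only, since PCR reads are not independent molecules. The sources do not say whether counting used strand, so overlapping and antisense genes are uncertain, as are genes that share reads with near-identical rows. Poly-A enrichment leaves transcripts without a tail out of scope. The genome of that build was not used here and the identifiers carry no positions, so no coordinates are given. Symbols were matched to a RefSeq gene table of assembly GRCz12tu for names and neighbours alone, and 21478 symbols were found. A further 176 symbols, found or not, stand on more than 1 row and carry their identifier where named. Gene lists were matched by plain symbol, so rows of these repeated symbols were left out of them.

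Columns were assigned to samples by genotype and number in the table header, where the wildtype columns are named casper. Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16, with filterByExpr (minimum count 10, 20229 genes kept), TMM factors, and the quasi-likelihood test with robust fitting, and p was adjusted by Benjamini-Hochberg over all genes tested; genes with adjusted p under 0.05 were called. Fold changes are log2 mutant over wildtype. Their standard error is the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 10.3%. CPM use TMM-scaled totals, and errors of CPM are SD over 3 libraries. The 39 gene lists, the tests, the rule for named genes and all settings not said to be added later were fixed before the data were examined. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes where at least 5 members were measured, adjusted over 38 lists, and again with an estimated correlation and with fry. The list of 13 mitochondrially encoded genes has no rows in the table and was not tested.

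The named genes are dnajc21; among called genes with a symbol whose groups do not overlap, the 8 highest and 8 lowest fold changes at a mean of at least 1 CPM and the 4 highest and 4 lowest at a mean of at least 50 CPM; and up to 4 called members of each list in order of adjusted p. Rows with clone or placeholder names were passed over, 30, 42, 1 and 3 in these 4 rankings. Sums over rows that share reads, and any gene said to be named after its values were seen, fall outside this rule.

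Rows that share reads were searched among 5732 rows with decimals in at least 4 libraries, as pairs whose values add up to whole numbers in all 6 libraries (tolerance 0.011). This gave 1000 pairs, and 0 after the decimals had been shuffled. The search, the fit with pairs summed and the fit without rows with decimals in at least 3 libraries were added after seeing the data. The alternatives fixed in advance were other scalings, other low-count filters, fitting without robust weights, the replicate number as a block, leaving out each library, DESeq2 1.42.0 and limma-voom. On simulated counts of 19923 genes, the fit recovered 53.7% of planted changes of 1.5-fold, 82.1% of 2-fold and 93.9% of 4-fold changes. False calls were 5.6%, or 10.4% where each gene kept its own dispersion. The simulation called 162 genes, far fewer than the data, which makes its adjusted threshold stricter. A list shifted by -0.40 was called, and 0 of 37 other lists were. Genes were simulated independently of each other, so this does not measure false list calls where members move together. All 300 planted pairs of rows were found, with 0 wrong. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.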

Results

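Whole zebrafish embryos were profiled by RNA sequencing at 48 hours post-fertilization, in 3 wildtype libraries and 3 libraries from homozygous dnajc21 mutants. Dnajc21 is a J-domain co-chaperone of the late steps of large ribosomal subunit assembly, and its human counterpart is mutated in an inherited bone marrow failure syndrome. Each library came from a pool of 30 to 50 embryos. The count table held 8600951, 10477853 and 10635686 counts in wildtype replicates 1 to 3, and 11798543, 9826927 and 10787119 in mutant replicates 1 to 3. The leading principal component of the log2 CPM, counts scaled to the TMM-adjusted library total, carried 45.9% of the variance and placed the 3 mutant libraries on one side and the 3 wildtype libraries on the other. The second carried 19.5% and spread the wildtype libraries, from -32.71 in replicate 2 to 38.73 in replicate 1, while the mutants lay between -5.19 and 3.99. The wildtype columns of the table carry the name casper, a pigment-deficient strain, and the labels do not give the background of the mutants. The labels also do not say whether pools came from separate clutches, so the p-values measure the spread between these libraries, which may be partly technical.

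The dnajc21 transcript was lower in mutants. It measured 26.1 ± 4.27 CPM in wildtype and 18 ± 1.48 CPM in mutant embryos (SD, n = 3 each), a log2 fold change of -0.55 (SE 0.12), and all 3 mutant libraries lay below all 3 wildtype libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00492). It was lower also with any 1 library left out. The mutants therefore kept most of the transcript, and the labels do not describe the lesion. Among 20229 genes tested, 1184 were higher and 1188 lower in mutants, 2372 in all, or 11.7%. Changes were mostly small. The median absolute log2 fold change of called genes was 0.51, 1363 of them changed by less than 1.5-fold, and 505 (239 higher, 266 lower) reached an absolute log2 fold change of 1. The groups did not overlap in 6165 tested genes, 30.5% of them, against 10% by chance for 3 against 3. The total fell to 1454, 1242 and 1356 genes without mutant replicate 1, 2 or 3, and DESeq2 called 1507.

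**Figure D1:**
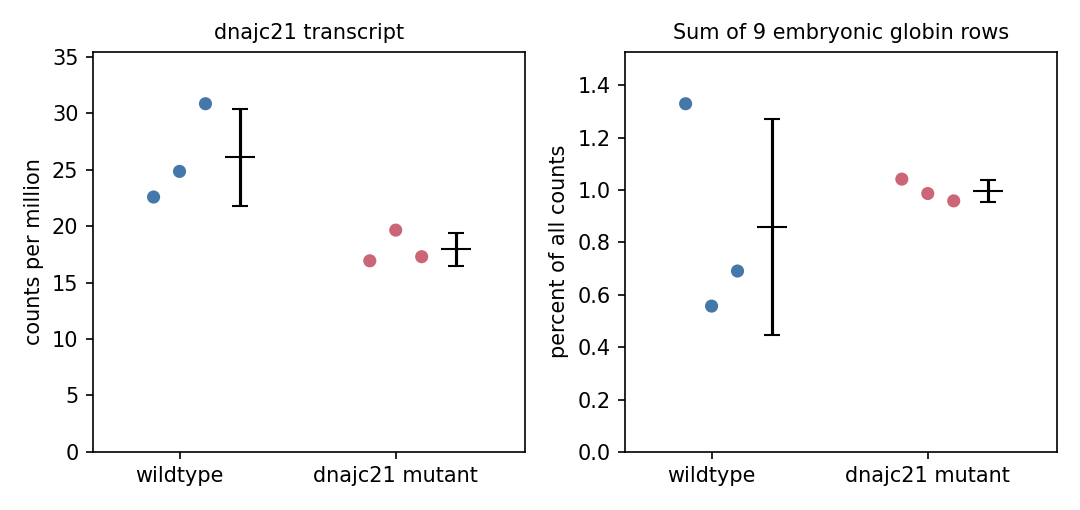
Left, dnajc21 transcript in CPM. Right, the summed share of 9 embryonic globin rows in percent of all counts. Points are single libraries (3 wildtype, 3 mutant), and bars give the mean ± SD. Every mutant library lies below every wildtype library for dnajc21, while the wildtype libraries spread widely for globin.

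The gene rfesd, for a Rieske-domain protein, rose from 0.281 ± 0.185 to 4.48 ± 0.343 CPM, and rxfp2a, for a relaxin-family peptide receptor, from 1.01 ± 0.089 to 11.6 ± 0.487 CPM (log2 fold changes 3.99 and 3.50; SE 0.39 and 0.20; edgeR adjusted p = 2.57e-06 and 3.95e-09). Other high values were the intelectin-like gene itln1l (3.95), acbd4, for an acyl-CoA-binding protein (2.95), cyp27a1.4, for a cytochrome P450 (2.94), gabrz, for a GABA receptor subunit (2.33) and the tapasin gene tapbp.1 (2.15). Reads of tapbp.1 were shared with tapbp.2, and those of itln1l and cyp27a1.4 were shared with other rows, so these 3 are uncertain. The gene znf1179, for a zinc finger protein, fell from 26.5 ± 5.97 to 1.74 ± 0.421 CPM, and aar2, for a splicing factor of U5 snRNP assembly, from 11.2 ± 0.820 to 1.29 ± 0.630 CPM (log2 fold changes -3.93 and -3.09; SE 0.21 and 0.24; adjusted p = 2.93e-08 and 1.36e-07). Other low values were pdk2b, for a pyruvate dehydrogenase kinase (-3.85), adh8a, for an alcohol dehydrogenase (-3.75), aftphb, for the trafficking protein aftiphilin (-2.51), cyp2x6, for a cytochrome P450 (-2.37), and crtac1a, for a matrix protein (-2.27). Counts of znf1179, adh8a and cyp2x6 were split with other rows. For pdk2b, with 5 counts in the 3 mutants together, the value was -3.14 without wildtype replicate 2 and -4.52 without mutant replicate 3. A further gene with a low value, ccdc36 (-3.80), shared its reads with kbtbd12, and the sum of both had a log2 fold change of 0.12. The ccdc36 call itself ended without wildtype replicate 3 (adjusted p = 0.0544), mutant replicate 1 (0.0689) or mutant replicate 2 (0.0786), and without mutant replicate 3, where both other mutants had 0 counts, its fitted value was -7.58; it was -3.19 without wildtype replicate 1 or mutant replicate 1.

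Among genes with a mean of at least 50 CPM, col28a2a, for a type XXVIII collagen, fell from 109 ± 4.24 to 30.0 ± 1.58 CPM (log2 fold change -1.86, SE 0.07, edgeR adjusted p = 6.38e-11). The gene rpia, for ribose-5-phosphate isomerase of the pentose phosphate pathway, which supplies ribose for nucleotides, fell from 86.1 ± 5.43 to 41.8 ± 4.89 CPM (log2 fold change -1.04, SE 0.09, adjusted p = 4.39e-07). The rida row LL0000023682 (-1.19), for a deaminase of reactive imines, shared reads with the other rida row, and the row of the gamma crystallin crygm2d14 (-1.23) has non-whole counts in all 6 libraries. The increases named in this class lay on rows with non-whole counts in all 6 libraries. They were rrm2 (3.16, described with the nucleotide genes), the alcohol dehydrogenase gene adh8b (1.52), the cathepsin L gene ctslb (1.57) and the hatching enzyme row he1.1 LL0000012013 (2.08). No partner row was found for adh8b. Added together, 5 cathepsin L rows that include ctslb were lower in mutants, at 614 ± 42.2 against 857 ± 91.8 CPM (log2 fold change -0.48, SE 0.075, edgeR adjusted p = 0.000552), the opposite direction to ctslb alone. Added together, the pair of he1.1 rows rose by 0.42 (SE 0.07, adjusted p = 0.000381). The he1.1 LL0000012013 call ended without mutant replicate 1 (adjusted p = 0.0577) or 3 (0.0565). The sums were formed after the data had been seen. Neither the cathepsin L nor the he1.1 sum is whole in any library. Both still share reads with rows outside them, so the direction of the transcripts stays uncertain.

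Blood genes addressed whether transcripts of blood lineages were lower, as the cytopenia in the title of the series raises. Erythroid genes were not lower as a group. Of 42 measured, 4 were higher and 2 lower (6 and 2 adjusted over the list alone), and 33 had positive log2 fold changes. The spectrin gene sptb rose from 70.9 ± 5.37 to 89.0 ± 2.77 CPM (0.33), the transferrin receptor tfr1a from 46.7 ± 1.80 to 60.4 ± 5.38 CPM (0.37), and znfl2a and the dematin gene dmtn also rose (0.73 and 0.37). The rows of znfl2a and dmtn have non-whole counts in 3 libraries each. The heme synthesis gene cpox (-0.41) and the GATA cofactor gene zfpm1 (-0.48) fell. The globins hbae1.1 (0.17, adjusted p = 0.836) and hbbe1.1 (-0.02, adjusted p = 0.984), the heme synthesis gene alas2 (0.77, adjusted p = 0.241) and gata1a, for the erythroid transcription factor (0.52, adjusted p = 0.165), did not pass. These 6 genes outside the naming rule, cpox and zfpm1 included, were chosen after their values were seen. The list was called higher by camera (adjusted p = 0.00392), with adjusted p = 0.83 with an estimated correlation. Wildtype replicate 1 weighed on all of this: without it 24 erythroid genes were called, against 3 without mutant replicate 1 and 2 without mutant replicate 2. The 9 embryonic globin rows took 1.33%, 0.557% and 0.691% of counts in wildtype replicates 1 to 3 and 1.04%, 0.987% and 0.959% in the mutants, means of 0.859% ± 0.413 and 0.996% ± 0.042 (SD, n = 3). The call of sptb ended without mutant replicate 2 (0.0522), and that of dmtn without wildtype replicate 2 (0.0536) or 3 (0.069) and mutant replicate 1 (0.0776) or 2 (0.0969).

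White blood cell markers moved in both directions. Of 26 neutrophil genes, the myeloperoxidase gene mpx fell from 25.2 ± 2.5 to 18.4 ± 0.342 CPM (log2 fold change -0.45, SE 0.10, edgeR adjusted p = 0.00673), while nccrp1 (0.42) and cebpd (0.35) rose, the same counts of 2 higher and 1 lower holding when adjusted over the list alone. Of 22 macrophage genes, the matrix-associated mfap4 rose from 7.81 ± 1.32 to 14.6 ± 3.04 CPM (0.91) on a row with shared reads, and the galectin lgals9l1 (-1.08, reads shared with lgals9l3) and the scavenger receptor marco (-0.92) fell, 1 higher and 2 lower also when adjusted over the list alone. Of 19 stem and progenitor genes, adgrg1, for an adhesion receptor, rose by 0.43 on a row with shared reads, 1 call also when adjusted over the list alone. Of 10 thrombocyte genes, thbs1b, for a thrombospondin, rose from 128 ± 2.5 to 201 ± 8.94 CPM (0.65) and the coagulation factor XIII gene f13a1b by 0.69, and 5 passed adjusted over the list alone. The thrombocyte list was called higher by camera (adjusted p = 0.00513), with adjusted p = 0.722 with an estimated correlation. Camera did not call the neutrophil (adjusted p = 0.877), macrophage (0.680) or progenitor lists (0.384). In the neutrophil list the median log2 fold change was -0.03 and the mean 0.01, and camera gave the lower direction. Of 7 lymphoid genes measured, edgeR called 0 (1 at an unadjusted p under 0.05), and DESeq2 and limma-voom 0 each; camera gave adjusted p = 0.573. Single libraries decided several calls. That of marco ended without any 1 of the 6 libraries (adjusted p of 0.0541 to 0.150), that of lgals9l1 without mutant replicate 1 (0.0573) or 2 (0.0778), and that of nccrp1 without mutant replicate 1 (0.0591). The cebpd call ended without wildtype replicate 1 (0.0621) or 3 (0.119), or mutant replicate 2 (0.123) or 3 (0.175). Without wildtype replicate 1, 4 thrombocyte genes were called. The count for progenitors was 2 without wildtype replicate 2 or mutant replicate 3. Macrophage genes numbered 1 without mutant replicate 1 or 2.

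Nucleotide genes addressed the altered nucleotide metabolism that the title of the series names. The folate enzyme genes mthfd1l, mthfd1a and mthfd1b serve the supply of carbon units for purines and thymidylate. The mitochondrial mthfd1l fell from 186 ± 6.51 to 104 ± 8.16 CPM (log2 fold change -0.84, SE 0.07, edgeR adjusted p = 5.00e-07) and mthfd1a from 24.1 ± 2.13 to 14.6 ± 2.71 CPM (-0.71), while mthfd1b rose from 75.6 ± 7.60 to 102 ± 4.47 CPM (0.42). The ribonucleotide reductase subunit rrm2b fell from 64.5 ± 5.14 to 47.1 ± 2.41 CPM (-0.45, SE 0.08, adjusted p = 0.00106). In all, 3 of 31 genes of deoxynucleotide synthesis and salvage were higher and 4 lower (3 and 6 adjusted over the list alone), rrm2 among the higher, whose reads are shared as described below. For de novo synthesis of purines and pyrimidines, 3 of 22 were higher and 2 lower (3 and 3 adjusted over the list alone). Of these, paics, for a bifunctional purine enzyme, rose from 534 ± 48.0 to 678 ± 41.4 CPM (0.35) on a row with shared reads, guk1a, for a guanylate kinase, rose by 0.28 and the CTP synthase gene ctps1b by 0.51, and cmpk, for a cytidylate kinase, fell by 0.37 on the log2 scale. Further called members of the nucleotide lists were adka (-0.31), gart (-0.28) and ampd1 (-0.83), named after their values were seen. Among 29 catabolic genes 2 were higher and 4 lower (4 and 4 adjusted over the list alone). The nucleotidase nt5c2b rose from 52.5 ± 1.86 to 73.7 ± 5.05 CPM (0.49) and the AMP deaminase ampd2a from 7.26 ± 2.11 to 13.2 ± 1.23 CPM (0.87). The nucleoside diphosphatase entpd5a (-2.04) and the xanthine dehydrogenase gene xdh (-0.50) fell. Camera called none of these 3 lists (adjusted p = 0.712, 0.710 and 0.820, in this order), and 0 passed with an estimated correlation (unadjusted p = 0.595, 0.778 and 0.742). For deoxynucleotide genes the median (0.03) and mean (0.10) were positive and camera gave the lower direction; without rrm2, left out after its values were seen, the median was 0.01 and the mean -0.006, with 2 higher and 4 lower of 30. For catabolism the median (0.02) and the mean (-0.03) differed in sign and camera gave the higher. Calls of ctps1b ended without wildtype replicate 3 (0.0661), mutant replicate 1 (0.113) or 3 (0.0823), those of guk1a without wildtype replicate 2 (0.055), mutant replicate 2 (0.0724) or 3 (0.0751), and those of xdh without wildtype replicate 2 (0.092) or 3 (0.0772), mutant replicate 2 (0.108) or 3 (0.118). De novo genes numbered 3 without mutant replicate 1, 2 or 3, and catabolic genes 3 without mutant replicate 2 or 3.

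The ribonucleotide reductase subunit gene rrm2 had 31.0 ± 11.3 CPM in wildtype and 276 ± 16.1 CPM in mutant embryos (log2 fold change 3.16, SE 0.33, edgeR adjusted p = 0.00955; 0.0541 with the replicate number as a block). Its reads were shared with the row LOC100330864, which moved the opposite way, from 476 ± 23.3 to 236 ± 24.0 CPM (-1.01, SE 0.07). Together both rows held 507 ± 19 and 512 ± 39.5 CPM, a log2 fold change of 0.015 (SE 0.066, adjusted p = 0.918), so the sum differed by less than the spread between replicates.

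**Figure D2:**
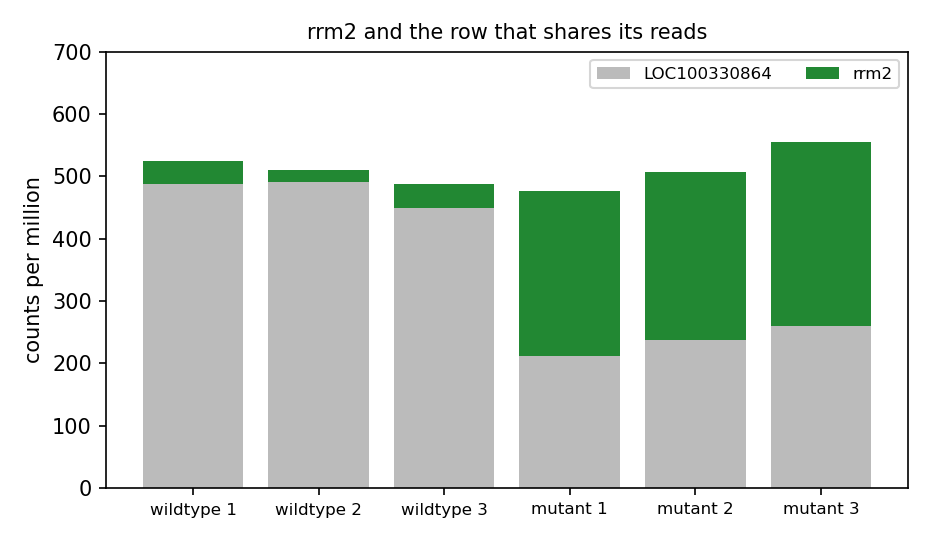
CPM of rrm2 (green) stacked on those of LOC100330864 (grey) in each of the 6 libraries. The rrm2 part lies between 17.9 and 37.7 in wildtype and between 264 and 294 in mutant libraries, while the full height of the bars overlaps between the groups.

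Ribosome assembly genes addressed the step in which Dnajc21 acts, and their changes were small. Of 45 large subunit assembly factors, rrp1 fell from 45.5 ± 3.66 to 31.8 ± 1.21 CPM (log2 fold change -0.52, SE 0.08, edgeR adjusted p = 0.000386; reads shared with LOC110437880), rpf1 (-0.34) and mrto4 (-0.33) fell, and gtpbp4 rose (0.20), 1 higher and 3 lower. Adjusted over the list alone, 3 were lower. The mrto4 row has non-whole counts in all 6 libraries. Camera gave adjusted p = 0.209. Of 61 small subunit and nucleolar factors 2 were higher and 4 lower (1 and 3 adjusted over the list alone), with nop10, of the box H/ACA particle, down from 27.7 ± 2.66 to 20.3 ± 0.914 CPM (-0.45) and nob1, the endonuclease of the last 18S rRNA cleavage, up from 40.7 ± 1.58 to 54.1 ± 4.05 CPM (0.41). The nucleolar factors nol10 (-0.36) and ltv1 (-0.29) also fell, as did polr1d (-0.40), while ubtf rose (0.26); polr1d and ubtf, both of RNA polymerase I transcription, were named after their values were seen. Camera called this list lower (adjusted p = 0.0231), with adjusted p = 0.83 with an estimated correlation; the call ended without wildtype replicate 3 (0.578) or mutant replicate 1 (0.119). Of 81 cytosolic ribosomal proteins, 0 were called by edgeR (6 at an unadjusted p under 0.05), 0 by DESeq2 and 0 by limma-voom, and edgeR called 13 without wildtype replicate 1, where camera also called the list (adjusted p = 0.0455 against 0.452). Large subunit factors numbered 7 without wildtype replicate 1, 2 without mutant replicate 1, and 1 without mutant replicate 2 or 3, and small subunit factors 2 without wildtype replicate 3 or mutant replicate 1, and 3 without mutant replicate 2 or 3. Calls of gtpbp4 ended without any 1 library other than wildtype replicate 1 (0.0863 to 0.228), and those of rpf1 without mutant replicate 2 (0.0562) or 3 (0.0931). The mrto4 call ended without wildtype replicate 3 (0.105) or mutant replicates 1 (0.118), 2 (0.0561) or 3 (0.103), ltv1 without the same libraries (0.0901, 0.162, 0.0747 and 0.0623), and nol10 without wildtype replicate 3 (0.0944) or mutant replicate 1 (0.0767) or 3 (0.106).

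Proliferation genes showed few calls. Of 49 replication genes the primase gene prim1 fell (log2 fold change -0.30, edgeR adjusted p = 0.0256), and of 49 mitosis genes the kinetochore gene spc24 fell from 26 ± 1.22 to 13.9 ± 0.448 CPM (-0.90) and the centromere gene cenpf rose from 65.2 ± 7.11 to 105 ± 1.62 CPM (0.69). Adjusted over the list alone, 0 replication genes and 2 mitosis genes passed, and camera gave adjusted p = 0.712 for both lists. The prim1 call ended without wildtype replicate 3 (0.114) or any 1 mutant (0.063 to 0.123), and mitosis calls numbered 4 without wildtype replicate 1. The prim1 row has non-whole counts in all 6 libraries.

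Of 26 endoplasmic reticulum chaperones, 12 were lower and the other 14 did not pass (19 lower and 1 higher adjusted over the list alone), and 1 had a positive log2 fold change. The secreted factor manf fell from 36.0 ± 4.32 to 22.0 ± 2.14 CPM (log2 fold change -0.71, SE 0.10, edgeR adjusted p = 0.000171) and the disulfide isomerase genes pdia4 (-0.61) and pdia3 (-0.39) and the calreticulin gene calr3a (-0.37) fell. Camera called the list lower (adjusted p = 8.44e-09), with adjusted p = 0.722 and unadjusted p = 0.0659 with an estimated correlation. Between 9 and 15 members were called without any 1 library. Nuclear genes of oxidative phosphorylation gave 14 lower and 2 higher of 79 (27 and 2 adjusted over the list alone), with ndufb3 down from 80.3 ± 12.7 to 51.2 ± 4.69 CPM (-0.64), uqcr10 (-0.37) and atp5f1d (-0.35) lower, and ndufv1, of complex I, up from 158 ± 10.1 to 215 ± 9.63 CPM (0.44). The other increase, cox6b1 (0.33), was named after its values were seen. Proteasome genes gave 6 lower of 43 (12 lower and 1 higher adjusted over the list alone), with psmb6 (-0.43), psma4 (-0.29), psmd7 (-0.28) and psmd4a (-0.28), the last pair on rows with shared reads. Camera called both lists lower (adjusted p = 2.54e-05 and 0.00392), with adjusted p = 0.83 for each with an estimated correlation, and the proteasome call ended without wildtype replicate 1 (0.143). Oxidative phosphorylation genes numbered 10, 8 and 7 without mutant replicates 1, 2 and 3, and proteasome genes 2, 1 and 3. The psmd4a call ended without wildtype replicate 1 (0.059) or any 1 mutant (0.0823 to 0.112), psma4 without mutant replicate 1 (0.0765) or 2 (0.0885), and psmd7 without mutant replicate 2 (0.0617).

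Of 37 lens genes 13 were lower (16 adjusted over the list alone), and 11 of the 13 were gamma crystallins of the crygm2d family, lens structural proteins, such as crygm2d3 (235 ± 22.2 to 130 ± 11.7 CPM, log2 fold change -0.86, SE 0.08, edgeR adjusted p = 2.66e-06) and crygm2d2 (170 ± 19.4 to 88.5 ± 7.99 CPM, -0.94). The crygm2d rows have non-whole counts, and on rows with whole counts camera gave adjusted p = 0.573 and 2 genes were called. Retina and photoreceptor genes gave 4 lower and 2 higher of 23, also when adjusted over the list alone. The photoreceptor transcription factor crx fell from 34.1 ± 3.76 to 14.1 ± 2.26 CPM (-1.26, SE 0.12, adjusted p = 2.39e-06), the phosphodiesterase gene pde6gb from 21.6 ± 3.99 to 9.28 ± 0.540 CPM (-1.21) and the transducin gene gngt2a by 0.95 on the log2 scale, while the retinal progenitor gene rx1 rose from 14 ± 2.05 to 21.7 ± 1.80 CPM (0.63). The photoreceptor gene otx5 (-0.93), named after its values were seen, was also lower. The crx row has non-whole counts in 3 libraries. Neuronal genes gave 10 lower of 39 (12 lower and 1 higher adjusted over the list alone), among them the synaptic genes vamp2 (-0.44), snap25b (-0.46) and sncb (-0.29) and the growth cone gene gap43 (-0.36). Liver and yolk syncytial layer genes gave 10 lower of 32 (10 adjusted over the list alone). The vitronectin gene vtnb fell from 124 ± 2.29 to 80.2 ± 1.18 CPM (-0.63), the transferrin gene tfa from 1256 ± 75.1 to 988 ± 75.4 CPM (-0.35), and apoa4b.1 (-0.38) and serpina1l (-0.51), both with shared reads, were lower. Of 13 pancreas and gut genes 3 were lower and 1 higher (4 and 1 adjusted over the list alone), with the intestinal fatty acid binding gene fabp2 down from 209 ± 6.0 to 148 ± 7.05 CPM (-0.50), fabp1b.1 (-0.27) and the somatostatin gene sst2 (-0.59) lower, and the carboxypeptidase gene cpa5 (0.56) higher.

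Camera called these 5 lists lower. Adjusted p was 2.90e-05 for lens, 0.0229 for retina, 0.0252 for neuronal, 0.0179 for liver and 0.0250 for pancreas and gut genes, with adjusted p of 0.799, 0.722, 0.83, 0.799 and 0.799 with an estimated correlation. The retina call ended without wildtype replicate 1 (0.132) or without non-whole counts (0.12), the neuronal call without wildtype replicate 1 (0.125), mutant replicate 2 (0.108) or 3 (0.131), the liver call without mutant replicate 1 (0.124), and the pancreas and gut call without wildtype replicate 1 (0.125), mutant replicate 2 (0.0802) or with no low-count filter (0.17). Neuronal genes numbered 6, 6, 5, 2 and 3 without wildtype replicates 1 and 2 and mutant replicates 1, 2 and 3, and liver genes 6 without mutant replicate 1. Pancreas and gut genes numbered 2 without wildtype replicate 2 or any 1 mutant. Calls of cpa5 ended without any 1 library other than wildtype replicate 1 (0.0731 to 0.154), of sst2 without wildtype replicate 2 (0.0521) or mutant replicate 3 (0.06), of fabp1b.1 without mutant replicate 1 (0.0655) or 2 (0.0934), of gap43 without mutant replicate 2 (0.089), and of sncb without mutant replicate 2 (0.0944) or 3 (0.0575).

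**Figure D3:**
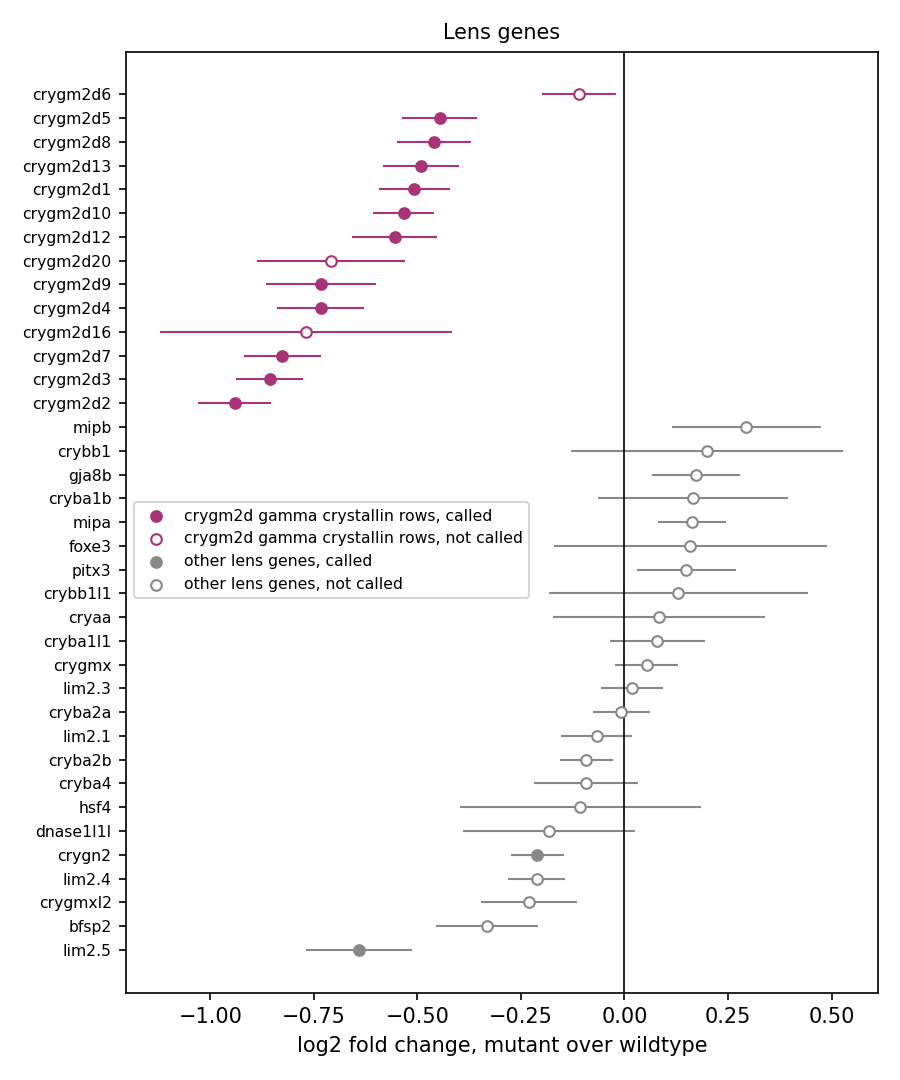
Log2 fold change, mutant over wildtype, of 37 lens genes, with bars of 1 SE; filled points passed the adjusted threshold. The 14 crygm2d gamma crystallin rows all lie below 0, and the other 23 lens genes lie on both sides of it.

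Of 30 cartilage and matrix genes 12 were higher (15 adjusted over the list alone) and 27 had positive log2 fold changes. The chondromodulin gene cnmd rose from 86.6 ± 3.71 to 118 ± 8.64 CPM (log2 fold change 0.45, SE 0.07, edgeR adjusted p = 0.000423), the cartilage collagen gene col9a1b from 328 ± 4.42 to 469 ± 68.2 CPM (0.51), and the fibrillar collagen genes col5a2a and col5a1 by 0.28 each. Camera called the list higher (adjusted p = 0.00133), with adjusted p = 0.799 with an estimated correlation. Skeletal muscle genes gave 11 higher and 3 lower of 39 (13 and 3 adjusted over the list alone). The contractile genes acta1a (461 ± 40.8 to 681 ± 44.1 CPM, 0.56) and myhz1.3 (3372 ± 242 to 4683 ± 319 CPM, 0.47) rose, both on rows with shared reads, while the muscle-determining transcription factors myod1 (11 ± 2.90 to 4.18 ± 0.391 CPM, -1.41) and myog (14 ± 1.21 to 7.87 ± 0.350 CPM, -0.83) fell, as did the parvalbumin gene pvalb2 (-0.21), named after its values were seen. Neural progenitor genes gave 6 higher and 1 lower of 31 (9 and 1 adjusted over the list alone), with her4.1 (0.61, shared reads), sox19b (0.49) and notch3 (0.29) higher and the radial glia gene fabp7a down from 503 ± 53 to 310 ± 25 CPM (-0.70). Camera did not call the muscle (adjusted p = 0.137) or progenitor list (0.0537), but called muscle without wildtype replicate 2 (0.00115) and progenitors without wildtype replicate 1 (0.00796) or 3 (0.0362) or mutant replicate 1 (0.0133), or with no low-count filter (0.0242). Cartilage genes numbered 7, 6 and 4 without wildtype replicate 3 and mutant replicates 1 and 2, and muscle genes 9, 8, 6 and 9 without wildtype replicate 2 and mutant replicates 1, 2 and 3. Neural progenitor genes numbered 4, 3 and 3 without wildtype replicate 2 and mutant replicates 2 and 3. The notch3 call ended without mutant replicate 2 (0.103) or 3 (0.056), and that of col5a1 without mutant replicate 2 (0.0568).

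In all, camera called 12 of 38 lists, 3 higher and 9 lower, with its preset correlation between genes. Regrouping the same 6 libraries in the 9 other ways of 3 against 3 gave 6 to 10 called lists. Those groupings mix the genotypes unevenly and keep part of the genotype difference, so these counts are not a null level for 12. With a correlation estimated from these libraries camera called 0, so a call with the preset correlation carries little weight alone. With the estimated correlation 1 list, thrombocyte genes, had an unadjusted camera p under 0.05 (p = 0.0307). The fry test, which asks whether a list moves one way on balance, called 0 lists in one direction (10 at an unadjusted p under 0.05; smallest adjusted p = 0.0735) and 35 lists for change in either direction. The latter does not compare a list with other genes. Among all 20229 genes tested, 5160 had an unadjusted edgeR p under 0.05, so the 35 show nothing particular to these lists.

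**Figure D4:**
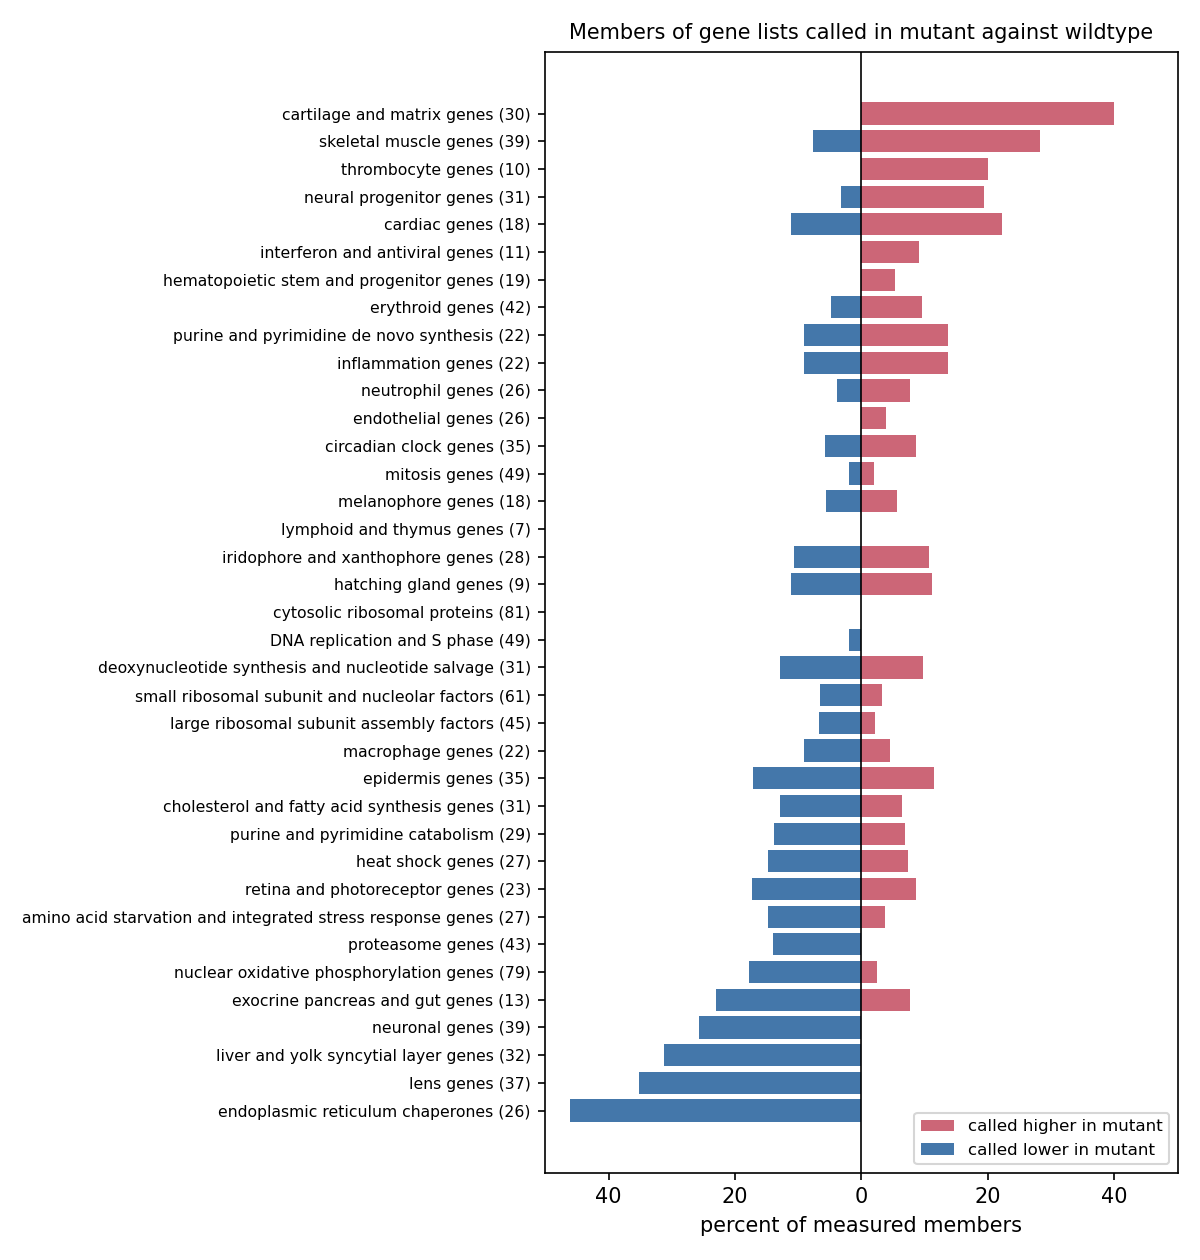
Share of the measured members of the gene lists shown, called higher (red, right) or lower (blue, left) in mutants, in percent; the number measured stands after each name. Endoplasmic reticulum chaperones (12 of 26), lens (13 of 37) and liver genes (10 of 32) have the longest bars to the left and cartilage genes (12 of 30) the longest to the right.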

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

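The alternatives with shared-read pairs summed and without non-whole counts were chosen after seeing the data; all others were planned. The dnajc21 transcript was lower and called under every alternative run, with log2 fold changes of -0.41 (without wildtype replicate 3) to -0.64 (without wildtype replicate 1). The 2372 called genes became 1507 with DESeq2 (1453 shared), and from 1242 (without mutant replicate 2) to 2658 (without wildtype replicate 1) with 1 library left out; the causes were not tested. The remaining alternatives gave 2014 to 2624. Genes with an absolute log2 fold change of at least 1 numbered 286 without non-whole counts, where fewer genes are tested, against 505, and 404 to 670 otherwise. The replicate number as a block gave 2470 genes (2246 shared). Libraries with the same number did not deviate together (correlations of -0.05, -0.003 and 0.022), so no sign of pairing by number was seen. With 3 libraries per group, centred on their group mean, a weak pairing could not be excluded.

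Camera called the same 12 lists under each scaling, the stricter filter and the block, and 12 with no low-count filter, where pancreas and gut genes lost their call (0.17) and neural progenitors gained one (0.0242). It called 10 to 13 with 1 library left out, 10 without non-whole counts, where the lens (0.573) and retina calls (0.12) were lost, and 0 with an estimated correlation, where the erythroid list had adjusted p = 0.83 (1.06e-12 to 0.0468 with 1 library left out and the preset correlation). The direction reversed, without a call on either side, for deoxynucleotide genes without wildtype replicate 2 (0.738; 0.732 to 0.891 with 1 library left out), large subunit factors without wildtype replicate 3 (0.925; 0.0595 to 0.925), neutrophil genes without wildtype replicate 1 (0.578; 0.578 to 0.984), and catabolism (0.925; 0.474 to 0.925) and de novo genes (0.925; 0.397 to 0.925) without wildtype replicate 3. It also reversed with 1 library left out for replication genes (range 0.274 to 0.996), epidermis (0.744 to 0.996), iridophore and xanthophore (0.357 to 0.996), melanophore (0.613 to 0.990) and hatching gland genes (0.737 to 0.996), for hatching gland genes without robust weights (0.956) and with the replicate block (0.807), and for epidermis without non-whole counts (0.202). The causes were not tested. Of 143 named genes, 9, 13 and 20 lost their call without wildtype replicates 1 to 3 and 27, 37 and 32 without mutant replicates 1 to 3, and 24 with DESeq2; 1, ccdc36, reversed, to 0.12 with shared-read pairs summed, where it is added to its partner row kbtbd12. Those lost with DESeq2 and described in these texts, 23 of the 24, were atf3, ccdc36, cpa5, ctps1b, dmtn, lgals9l1, ltv1, marco, mrto4, nfil3-6, nfkb2, nol10, pnp4a, prim1, psat1, rab32a, rorab, rpf1, slc2a15b, slc7a5, sst2, stab1 and xdh (0.0503 to 0.19). Also lost were atf3 (0.0733), cebpd (0.061) and xdh (0.0513) with limma-voom, cebpd (0.0608), cpa5 (0.0549), gtpbp4 (0.0772) and psat1 (0.0563) without robust weights, and cebpd (0.12), gtpbp4 (0.0564), marco (0.0646) and rrm2 (0.0541) with the replicate block. The gtpbp4 call ended also with no low-count filter (0.0608) and with library size only (0.0621), and those of psmd4a (0.121) and rrm2 (0.918) with shared-read pairs summed.

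Counts per list that moved by over 1.5 times with DESeq2 included 0 for replication and endothelial genes, 1 for integrated stress response, iridophore and xanthophore, macrophage and melanophore genes, 2 for large subunit factors and pancreas and gut genes, and 3 for small subunit factors, de novo and circadian genes. Erythroid genes numbered 11 with limma-voom or without robust weights, integrated stress response genes 3 without robust weights, and iridophore and xanthophore genes 3 with limma-voom. Stem and progenitor genes numbered 2 with no low-count filter or with the block. Without non-whole counts they were 0 for replication, 1 for macrophage and hatching gland, 2 for lens, 4 for epidermis, liver and thrombocyte and 8 for muscle genes.

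At this depth and number of libraries, 53.7% of simulated 1.5-fold changes were recovered, so differences of this size or smaller can be missed. The simulation called 162 genes, against 2372 in the data. Fewer changed genes make the adjusted threshold stricter, so recovery in the data may be higher, and the share missed is not known.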

Other observations

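The sums of rows, the neighbour counts and the lens and cartilage comparisons below were chosen only after the results were seen; the counts of other splits and the list tests were planned. Stress genes moved both ways. Of 27 heat shock genes, cytosolic and other, 2 were higher and 4 lower (4 and 7 adjusted over the list alone). The heat shock factor gene hsf1 fell from 36.9 ± 1.76 to 24.6 ± 0.921 CPM (SD, n = 3 each; log2 fold change -0.59, edgeR adjusted p = 0.000152), the mitochondrial chaperonins hspe1 (-0.40) and hspd1 (-0.42) fell, and the co-chaperone gene bag3 rose (0.54). Camera gave adjusted p = 0.177, and 0.00305 without wildtype replicate 1, where 13 members were called. Of 27 genes of amino acid starvation and the integrated stress response 1 was higher and 4 lower, also adjusted over the list alone. The serine synthesis genes phgdh (-0.36) and psat1 (-0.21) and the amino acid transporter gene slc7a5 (-0.30) fell, and the transcription factor atf3 rose (0.58). Camera gave adjusted p = 0.512. Calls numbered 1 without wildtype replicate 2 or mutant replicate 3, 2 without mutant replicate 1 or 2, 3 without wildtype replicate 3 or without robust weights, and 1 with DESeq2. The atf3 call ended with DESeq2 (0.0543) and limma-voom (0.0733), and without wildtype replicates 1 (0.061), 2 (0.0824) or 3 (0.122) or mutant replicates 2 (0.0928) or 3 (0.175, fold change 0.37). That of slc7a5 ended without wildtype replicate 2 (0.0849) or any 1 mutant (0.0504 to 0.150), and that of psat1 without any 1 library other than wildtype replicate 1 (0.0625 to 0.169).

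Of 22 inflammation genes 3 were higher and 2 lower (5 and 2 adjusted over the list alone). The itaconate synthesis gene irg1l rose from 12.8 ± 1.17 to 24.7 ± 3.61 CPM (log2 fold change 0.94, edgeR adjusted p = 6.21e-05), and socs3a (0.94), a feedback inhibitor of cytokine signalling, also rose; the lipocalin gene lcn15 (-1.30) and nfkb2 (-0.45) fell. Camera gave adjusted p = 0.129, and 0.00419 without mutant replicate 1. Calls numbered 3 without wildtype replicate 3 or mutant replicate 2, and 2 without mutant replicate 3. The lcn15 call ended without mutant replicate 3 (0.0543), and that of nfkb2 without any 1 library other than wildtype replicate 1 (0.0541 to 0.119). Of 11 interferon genes irf9 rose (0.87; camera adjusted p = 0.686), 1 call also adjusted over the list alone, lost without mutant replicate 2 (0.0606). Of 26 endothelial genes the scavenger receptor stab1 rose (0.38; camera adjusted p = 0.0842), and 0 passed in edgeR adjusted over the list alone. The stab1 call ended without wildtype replicates 1 (0.0585) or 3 (0.0601) or any 1 mutant (0.0539 to 0.105). Of 18 cardiac genes 4 were higher and 2 lower (5 and 3 adjusted over the list alone), with the calcium pump atp2a2a (-0.55) and the myosin light chain myl4 (-0.70) lower and the myosin genes myh7l (0.36) and myh7 (0.33), on rows with shared reads, higher. Camera gave adjusted p = 0.190. Cardiac calls numbered 2 without mutant replicate 2, where myl4 (0.0509) and myh7 (0.0796) were lost.

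Of 31 cholesterol and fatty acid synthesis genes 2 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.556). The sterol synthesis genes fdps (-0.44), acat2 (-0.47) and dhcr7 (-0.64) fell and the regulator srebf1 rose (0.46, shared reads). Calls numbered 3 without wildtype replicate 3 or mutant replicate 3, and the dhcr7 call ended without wildtype replicate 3 (0.0834) or mutant replicates 2 (0.0724) or 3 (0.0538). Of 35 circadian genes 3 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.276). The repressor gene nr1d2a (-0.88) and rorab (-0.40) fell and per3 (0.43) and nfil3-6 (0.57) rose. Calls numbered 2 without mutant replicate 1 and 3 without mutant replicate 3; that of nfil3-6 ended without mutant replicates 1 (0.0556) or 3 (0.0677), and that of rorab without wildtype replicate 1 (0.0884) or any 1 mutant (0.0518 to 0.129). Of 35 epidermis genes 4 were higher and 6 lower (8 and 8 adjusted over the list alone; camera adjusted p = 0.877; median 0.005, mean -0.017, camera lower). The keratin gene krt8 rose from 799 ± 25.3 to 1138 ± 35.9 CPM (log2 fold change 0.51) and krt18a.1 by 0.32, while the claudin gene cldne (-0.37) and anxa1c (-0.41, shared reads) fell. Epidermis calls numbered 5 without mutant replicate 1 and 6 without mutant replicate 2. Of 9 hatching gland genes ctslb was higher and agr2 (-0.39) lower, also adjusted over the list alone. Camera gave adjusted p = 0.859 and the lower direction (median -0.12, mean 0.01). The listed gene he1.1 stands on more than 1 row and was therefore not among the 9. Its rows added together rose by 0.42 (edgeR adjusted p = 0.000381), and the list values leave these rows out. The ctslb row has non-whole counts, and without non-whole counts agr2 alone was called. Added together, 5 cathepsin L rows that include ctslb were lower (-0.48, edgeR adjusted p = 0.000552). Neither sum is whole in any library, so reads shared with rows outside the sums may move both values.

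Of 18 melanophore genes the vesicle gene rab32a rose (0.60) and the melanin synthesis gene tyrp1b fell (-0.37), also adjusted over the list alone (camera adjusted p = 0.718). Both were lost without mutant replicates 1 (0.125 and 0.0731) or 3 (0.123 and 0.104). That of rab32a ended also without wildtype replicates 1 (0.0587) or 2 (0.0841), and that of tyrp1b without wildtype replicate 1 (0.0534) or mutant replicate 2 (0.0553). Of 28 iridophore and xanthophore genes 3 were higher and 3 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.556), with slc2a15b (0.39) and paics (0.35) higher and pnp4a (-0.39) and xdh (-0.50) lower. Calls numbered 2 without wildtype replicate 3, mutant replicate 1 or mutant replicate 3, and 1 without mutant replicate 2. The pnp4a call ended without wildtype replicates 1 (0.0695) or 3 (0.101) or any 1 mutant (0.0973 to 0.116), that of slc2a15b without wildtype replicate 2 (0.0603) or any 1 mutant (0.0541 to 0.114), and that of xdh without wildtype replicates 2 (0.092) or 3 (0.0772) or mutant replicates 2 (0.108) or 3 (0.118). Other members completing counts, named after their values were seen, were hspb9 (0.41), hspa4a (-0.51), cth (-0.27), socs3b (0.69), nppb (0.74), tnnc1a (0.48), insig1 (0.30), cyp51 (-0.63), tefb (0.40), cdh1 (0.32), tp63 (0.26), ltk (0.44) and gart (-0.28). In wildtype replicate 2, 18 rows took 4.95% of counts, against 0.093% to 0.129% in the other libraries; in counts per total unscaled by TMM, zgc:158463 measured 14601 CPM there and 260 to 368 CPM elsewhere, and CT027638.1 14318 CPM and 310 to 429 CPM.

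The 6 libraries split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2372 genes, and the highest other split 1; for genes with an absolute log2 fold change of at least 1 these were 505 and 1, and for lists called by camera 12 and 10. In each case 1 split, the real one, gave a value as large. Every other split mixes both genotypes in each group, so a genotype difference widens the spread within groups there. Few called genes in those splits are then built in, and their counts are not a null level for 2372 or 505. Part of the genotype difference also stays in each such split, so the list counts are not a null level for 12.

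The rrm2 increase sits on a row that shares reads with LOC100330864, and both rows added together had a log2 fold change of 0.015, so a different split of the same reads, as a sequence difference between families would give, is a candidate explanation. More transcript from the pair is argued against, since the sum plus 2 SE reaches 0.147. Among 505 large changes, 249 (49.3%) lay on rows with shared reads, against 397 (21.3%) of 1867 smaller called ones (odds ratio 3.6, 95% interval 2.91 to 4.45, Fisher's exact test p = 1.77e-33), and of 39 detected pairs with a large change 13 stayed large when summed. Shared reads are not the whole cause of large changes, since 256 lay on rows with whole counts. What makes the rrm2 reads split differently was not tested further.

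Large changes on rows with whole counts lay next to each other along chromosomes (RefSeq order, assembly GRCz12tu) in 9 pairs, such as mymk and slc2a8 (-1.21 and -1.09) and ponzr3 and ponzr4 (1.33 and 1.32), against 2.35 with shuffled positions (permutation p = 0.00053). Other pairs moved in opposite directions, slc5a11 and e4f1 (2.54 and -1.16) and lins1 and cers3a (-1.23 and 1). The pairs are not all separate, since slc2a8 was also counted with lcn15 (-1.30). Different haplotypes in the mutant and wildtype families could give such neighbours, a strain difference that the name casper leaves open. Pigment genes were not raised in mutants as sets. Melanophore genes gave 1 higher and 1 lower of 18 (median -0.07), and iridophore and xanthophore genes 3 and 3 of 28 (median 0.05). For these genes, the values argue against fully pigmented mutants compared with casper. Other haplotype differences stay open. The haplotype around dnajc21 is not the whole cause, as 8 pairs lay on other chromosomes; near dnajc21, 24 of 120 genes were called, against a mean of 13.8 in other windows, and 5.6% of windows had as many. Neighbours regulated together stay open, since smaller changes also had more neighbours than shuffled, by 1.29 times against 3.82 for large ones. The labels name no common parents, so a difference of haplotype and the dnajc21 genotype may run together across these libraries.

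Of 14 listed crygm2d gamma crystallin rows 11 were lower, while most other lens genes were not called. Shared reads among the crygm2d rows do not account for this, since 19 crygm2d rows added together fell from 3612 ± 395 to 2369 ± 246 CPM (SD, n = 3; log2 fold change -0.61, SE 0.10, edgeR adjusted p = 0.00736). Reads shared between these rows and rows of other names were not tested and stay open. A lens smaller in all its transcripts is argued against by the other 23 lens genes, with a median of 0.02. Of these, 2 were lower, crygn2 (-0.21) and lim2.5 (-0.64), named after their values were seen. The SE of this median, 0.06, treats the genes as independent and leaves out the spread between libraries. In the list of cartilage and matrix genes 12 were called higher and 0 lower. These were 7, 6 and 4 higher without wildtype replicate 3 and mutant replicates 1 and 2. That list also holds fibrillar collagen genes such as col5a1, and its members move together (estimated correlation 0.314). With that correlation camera gave adjusted p = 0.799, so these calls do not exclude a delay common to all tissues. A delay of the lens, or of the eye and nervous system, may remain. Of 23 retina and photoreceptor genes 4 were lower, among them crx (-1.26), pde6gb (-1.21) and gngt2a (-0.95), and 2 higher, among them rx1 (0.63). In the neuronal list 10 genes were lower (6, 6, 5, 2 and 3 without wildtype replicates 1 and 2 and mutant replicates 1, 2 and 3). In the neural progenitor list 6 were higher (3, 2 and 2 without wildtype replicate 2 and mutant replicates 2 and 3) and 1, fabp7a (-0.70), was lower. With an estimated correlation camera gave adjusted p = 0.722 for the retina list and 0.83 for the neuronal and progenitor lists each. These calls therefore do not decide the question. A strain difference in the crygm2d family may also remain, which was not tested.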
